A study of Zea mays with 48 samples.

How the data were processed

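Maize B73 plants about 6 weeks old were turned on their side by 90 degrees, and the pulvinus, the stem joint that bends the shoot upright again, was collected after 2, 5, 15, 30 and 60 min. Each pulvinus was cut lengthwise into an upper side, which elongates slowly, and a lower side, which elongates fast. Vertical plants gave left and right sides as controls. Each time point pooled 6 pulvini, and both sides of a time point came from the same plants. Each tissue powder was split into an aliquot for total RNA and an aliquot for polysomal RNA, the RNA bound to several ribosomes. Hybridization to the Affymetrix GeneChip Maize Genome Array gave 48 arrays in 24 groups of 2, and the 2 arrays of a group came from 2 growing seasons.

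The deposited table holds signal intensity on a linear scale, which the authors made with GCOS per the processing notes of the labels. No GCOS version, scaling target or detection call was used here. The 2% trimmed mean of the 48 arrays lay between 495.8 and 499.1, with a largest departure of 0.44% from their median, so the arrays were taken as scaled and used as deposited. The table has 17545 probe sets, signals up to 14970.1 and 10 zeros. Median signal per array ran from 174.3 to 216.9, and 15.0% to 22.4% of probe sets per array lay below 16. The number of arrays limits the precision of every value.

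Values were taken as log2 of the signal plus 16. Probe sets with a mean log2 value under the 40th percentile were left out, which left 10527. The planned check of RNA quality on control probe sets was not run, since the table has no control probe sets of that kind. The annotation table names a gene for 1453 probe sets. Of these, 1452 have 1 gene and 1 has several, and 16092 have none. The 1452 probe sets cover 1108 Entrez genes, 1377 of them were found in the RefSeq annotation of the B73 assembly Zm-B73-REFERENCE-NAM-5.0 and 75 were not. After the filter 920 named probe sets of 773 genes remained beside 9607 without a listed gene. Genes carry the name of the annotation table, with the locus symbol where a name belongs to several loci.

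Models were fitted with limma 3.58.1 (statmod 1.5.0, R 4.3.3) through lmFit and eBayes with a trend, with 12 groups and the season as a fixed effect. Separate fits covered the 24 total RNA arrays, the 24 polysomal arrays and the 24 differences of log2 polysomal minus log2 total signal of the same powder. Each left 11 residual degrees of freedom. A probe set passed when its Benjamini-Hochberg adjusted p lay under 0.05. Comparisons were the lower minus the upper side, the right minus the left side of vertical plants, the mean of both sides minus the mean of the vertical sides, each per time point and averaged over 5 times, and polysomal minus total RNA. SE is that of the limma contrast. Differences of the polysomal over total ratio were also tested over the 5 times together with limma's moderated F.

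The season was kept in the fit. Array labels give a repetition number and no season, so an array called labelled season 1 carries the label of repetition 1. The repetition number was taken as a growing season shared by all groups. In a check of that pairing, departures from the group mean in season 1 were correlated across probe sets between groups, with a median r of 0.621 over 66 pairs of groups in total RNA (0.505 to 0.892) and 0.661 in polysomal RNA (-0.0268 to 0.896). Both sides of a plant pool also resembled each other. The correlation within a pool, by duplicateCorrelation, was 0.575 in total RNA, 0.381 in polysomal RNA and 0.195 in the powder differences. A fit with the plant pool as a random block was run for each comparison, and its value stands beside the main counts.

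Named genes follow a rule written before the data were examined. For each contrast averaged over times, and for polysomal against total RNA, they are the 10 highest and 10 lowest log2 changes among probe sets past the threshold with the same sign in both seasons and 1 gene, with the brightest probe set per gene. For single times they are the 3 highest and 3 lowest, and where none passed, the 6 smallest p values are given as values. Each gene list past its test adds its 3 leading members. Calreticulin, calmodulin, invertase and inositol or phospholipid enzyme genes, followed earlier in this organ, were named whatever their test. A gene named once may also have its values at other times given.

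Of 23 gene lists fixed before the data were examined, 18 had at least 5 probe sets after the filter. The others, among them gibberellin, circadian clock and light signalling, seed and pollen markers and organelle-encoded transcripts with 2, 2, 3 and 1 probe sets, were not tested. Lists matched symbols and synonyms by pattern, so some hold members of another function, such as actin-depolymerizing factors in the auxin list, and a run without those members was added later. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 18 lists of a contrast, and again with an estimated correlation. Of 67 list calls in the contrasts reported other than season, 0 held with an estimated correlation, with adjusted p from 0.117 to 0.915. The list calls between seasons are given apart. Camera's preset correlation called all 67.

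Each result was computed again with pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, a fit without the season, eBayes without a trend, the plant pool as a random block, a model of all 48 arrays with the powder as a random block, each season alone, each side against 1 vertical side, and leaving out each array in turn. After the data were seen, fits without 1 doubted polysomal array, with and without the pool block, a pool block on the powder differences, and 3 other settings of the list test were added. So were the pool means and the fits without that array for the season. Of 100 regroupings per averaged contrast, drawn with a fixed seed and with the real one counted among them, those with as many probe sets past the threshold were counted.

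The tests were tried on simulated data of 10527 probe sets with changes put into 100 at each size. With independent pools, 94% of changes of 1 log2 unit and 67% of changes of 0.5 were recovered for reoriented against vertical plants, averaged over times. For the lower against the upper side these were 100% and 89%, and at the single time of 15 min 68% and 21%. With a pool correlation of 0.5, the fit with season alone made 87 false calls for reoriented against vertical plants, and the pool block made 7. For the lower against the upper side, averaged over times, these were 0 and 13. At 15 min the fit with season alone then recovered 8% of lower against upper changes of 0.5, and the pool block 43%, with 1 and 4 false calls. In 10 draws without any change the fits made up to 14 and 0 calls for reoriented against vertical plants, and 0 in both for the lower against the upper side. A list with a change put into it was recovered by camera, and 0 of the other lists passed. Simulated probe sets were drawn independently of each other, so that trial cannot show how often lists of correlated members pass falsely.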

Results

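The series asked how gene expression and ribosome loading change in the maize pulvinus after the plant is laid horizontal, and how the fast growing lower side differs from the slow growing upper side. The 48 arrays form 12 groups of 2 in each kind of RNA, upper and lower sides at 5 times and left and right sides of vertical plants. Growing season accounted for 30.1% of the variance over the tested probe sets, time point for 22.9%, kind of RNA for 18.8% and the side within a time point for 4.15%. The polysomal array labelled upper side, 5 min, season 1 stood apart. It correlated at r = 0.981 across probe sets with both 5 min polysomal arrays of season 2 and at 0.903 with the lower side of its own pool, against 0.973 to 0.992 for the sides of the other 23 pairs, from 12 plant pools in each kind of RNA. The main counts from polysomal RNA are therefore also given without it. Genes are not independent replicates, and these r describe arrays.

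**Figure D1:**
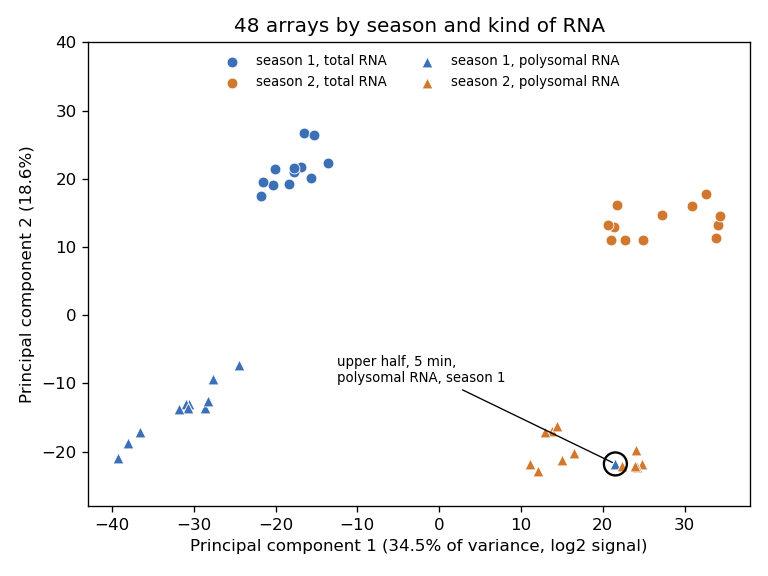
Principal components 1 (34.5% of the variance) and 2 (18.6%) of the log2 signal of the 48 arrays, coloured by season, with circles for total and triangles for polysomal RNA. The ringed array is labelled season 1 and lies among the season 2 polysomal arrays.

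In total RNA of reoriented against vertical plants, averaged over 5 times and both sides, dbf1, a factor that binds drought-responsive promoter elements, rose by 1.11 log2 units (SE 0.12, 20 reoriented and 4 vertical arrays, adjusted p = 0.000423), and SAG (LOC542202) rose by 1.34 (SE 0.21, adjusted p = 0.00355). The glutathione S-transferase genes gst12 and gst30 were higher by 1.56 (SE 0.36) and 1.43 (SE 0.28), and the aquaporin gene tip2 by 1.25 (SE 0.29). Also higher were acco20, which encodes an enzyme of ethylene synthesis, by 0.97 (SE 0.17), the beta-glucosidase gene glu1 by 0.93 (SE 0.16), and the phosphate transporter genes pht1 and pht7 by 0.92 (SE 0.20) and 0.89 (SE 0.20). LOC100125656 was higher by 1.26 (SE 0.32). Of genes that were lower, the small GTPase gene rop4 (LOC542758) changed by -0.56 (SE 0.11), LOC542763 by -0.59 (SE 0.11), LOC542694 by -0.38 (SE 0.10) and pfk1 by -0.28 (SE 0.07). All 14 genes passed limma's adjusted p and had the same sign in both seasons, as the naming rule requires. These SE and adjusted p count both sides of a plant pool as separate, and the 4 vertical arrays come from 2 plant pools. With the plant pool as a random block 11 of the 14 missed the threshold. A pair of probe sets without a listed gene, chosen after their values were seen, rose further, by 3.31 (SE 0.50) and 3.16 (SE 0.35).

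In total RNA 372 of 10527 probe sets passed for the mean of the 5 times, 266 higher and 106 lower in reoriented plants. With the plant pool as a random block 45 passed, 44 higher and 1 lower, and 3 of the 14 named genes were among them: SAG, dbf1 and glu1. With the season (replicate block) left out of the fit 52 passed. The calls of dbf1 and SAG stood without any 1 array, while 12 of the 14 named genes lost theirs without at least 1 array, with adjusted p up to 0.236. Without the left vertical array of season 2 gst12 fell to 0.87, tip2 to 0.73 and LOC100125656 to 0.70, and without the right one pht1 fell to 0.61. In the 2 seasons gst12 changed by 0.27 and 2.85. The count moved by over 1.5 times without either vertical array of season 1 (left 242, right 166) or season 2 (left 124, right 79).

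The response differed in timing between genes. The gene dbf1 had risen by 1.44 (SE 0.16) at 2 min and 1.19 at 5 min, stood at 1.74 at 15 min and 0.93 at 30 min, and at 60 min its change of 0.27 did not pass. SAG and the calcium-dependent protein kinase gene CDPK1 had not passed by 5 min and rose by 2.55 (SE 0.27) and 2.02 (SE 0.23) at 15 min. At 30 min SAG stood at 1.81 and CDPK1 at 1.26, and at 60 min SAG at 1.35 while CDPK1, at 0.71, did not pass. Total RNA of tip2 rose by 1.82 (SE 0.37) at 15 min. Total RNA of gst30 rose by 2.12 (SE 0.36) at 30 min and 1.54 at 60 min. Its log2 signal was already higher at 15 min, at 8.05 to 9.20 against 5.61 to 7.9 in vertical plants. At 30 min gst12 rose by 1.70 (SE 0.47), against 1.56 for the mean of the 5 times. Times are given by the naming rule, so a time not given for a gene is not a time without change. The gene aos1, whose product makes allene oxide for jasmonate, rose by 0.70 at 30 min and 1.14 (SE 0.16) at 60 min. The gene opr7, for a later enzyme of that pathway, rose by 0.49 (SE 0.11) at 60 min. PLD1, a phospholipase D gene, rose by 0.67 (SE 0.12) at 30 min and 0.51 (SE 0.12) at 60 min. The aquaporin gene pip2c fell by 0.72 (SE 0.19) at 15 min and 0.71 at 30 min, and the histone gene his1 by 0.70 and 0.75. PPCK1, a kinase of phosphoenolpyruvate carboxylase, fell by 0.74 (SE 0.16) at 15 min, and OEE3, of the oxygen-evolving complex, by 1.01 (SE 0.22) at 30 min. At 60 min LOC542763 was at -0.79, rop4 (LOC542758) at -0.61, LOC542694 at -0.54 and pht1 at 1.24, each past the threshold.

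In total RNA 7 probe sets passed at 2 min (6 higher), 6 at 5 min (6 higher), 953 at 15 min (539 higher, 414 lower), 539 at 30 min (348 and 191) and 419 at 60 min (280 and 139). After quantile normalization 60 passed at 2 min (35 higher, 25 lower) and 23 at 5 min (15 and 8). At 2 min the named ones were dbf1, glu1 (1.31, SE 0.20) and rop4 (LOC542758, -0.84, SE 0.14), and at 5 min dbf1 alone. With the plant pool as a random block 1, 2, 293, 113 and 34 passed, and dbf1 was the 1 at 2 min and, with a probe set without a listed gene (2.15), among the 2 at 5 min. With the pool block dbf1 passed from 2 to 30 min, SAG and CDPK1 at 15 and 30 min, tip2 at 15 min (adjusted p = 0.0427), aos1 at 60 min (adjusted p = 0.0493) and PLD1 at 30 min (adjusted p = 0.0427). The other named calls at single times were lost with it, from OEE3 at 30 min (adjusted p = 0.0613) to gst30 at 60 min (adjusted p = 0.328). Without the replicate block 1, 3, 266, 87 and 28 passed. The count at 2 min was 144 without the left vertical array of season 1 and 1 without the upper, lower or right vertical array of season 2. It was 63 and 0 at 5 min without the upper arrays of seasons 1 and 2, where dbf1 then had an adjusted p of 0.0802, and 545 at 15 min without the upper array of season 2. Without the lower array of season 1 it was 151 at 30 min and 127 at 60 min. At 30 min gst12 was 1.02 without the left vertical array of season 2, and his1 was -0.49 without the upper array of season 1. The times share the vertical controls.

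**Figure D2:**
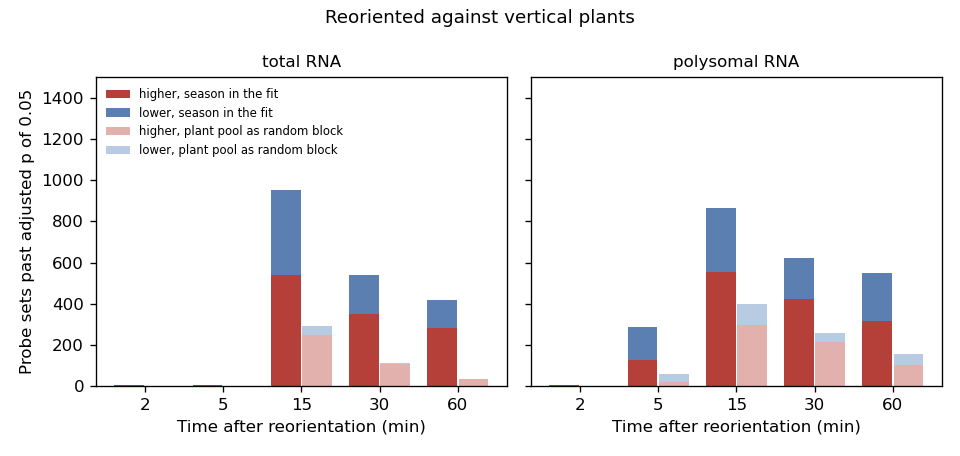
Number of probe sets past an adjusted p of 0.05, of 10527, in reoriented against vertical plants at each time (min), for total and polysomal RNA. Dark bars are the fit with season alone, pale bars the fit with the plant pool as a random block; at 15 min these were 953 and 293 in total RNA and 865 and 399 in polysomal RNA.

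In polysomal RNA the averaged response again had tip2 (1.81, SE 0.40), SAG (1.37, SE 0.16), gst12 (1.25, SE 0.32), dbf1 (1.24, SE 0.19), gst30 (1.21, SE 0.21), pht1 (0.94, SE 0.15), glu1 (0.92, SE 0.24) and pht7 (0.88, SE 0.23) among genes that rose. LOC606403 rose by 0.97 (SE 0.23) and CDPK1 by 0.85 (SE 0.15). Genes that fell were mpao1, for a polyamine oxidase (-1.07, SE 0.23), rs2, for a MYB factor of leaf patterning (-0.84, SE 0.22), expA3, for an expansin that loosens cell walls (-0.82, SE 0.14), gar2 (-0.79, SE 0.21), and dwarf3, of gibberellin synthesis (-0.79, SE 0.20). Further genes that fell were lkrsdh1, of lysine breakdown (-0.67, SE 0.14), LOC542763 (-0.48, SE 0.09), met2 (-0.47, SE 0.12) and yptm3 (-0.20, SE 0.05). Of these 19 genes, tip2, SAG, dbf1, gst30, pht1, CDPK1, mpao1, expA3 and lkrsdh1 also passed with the plant pool as a random block. With the doubted array left out as well gst30, mpao1, expA3 and lkrsdh1 missed, with adjusted p of 0.0867, 0.0644, 0.0606 and 0.0601.

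In polysomal RNA 454 probe sets passed for the mean (304 higher, 150 lower), 152 with the plant pool as a random block and 116 without the replicate block. Without the doubted array 586 passed, and 149 with the pool block as well. The count fell to 277 without the right vertical array of season 1, and to 178 and 117 without the left and right ones of season 2. The calls of SAG, dbf1, gst30, pht1 and CDPK1 stood without any 1 array, and the other 14 lost theirs without at least 1, with adjusted p up to 0.272. Without the left vertical array of season 2 tip2 fell to 1.18, gst12 to 0.66 and glu1 to 0.51, and gar2 stood at -0.52.

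Over time in polysomal RNA, dbf1 rose by 1.64 (SE 0.24) at 2 min, 1.12 at 5 min, 1.82 at 15 min and 1.18 at 30 min. SAG rose by 2.53 (SE 0.21) at 15 min, 2.09 at 30 min and 1.55 at 60 min. At these times CDPK1 rose by 1.61, 1.34 and 0.92 and gst30 by 1.61, 2.04 (SE 0.27) and 1.20. The gene tip2 rose by 2.09 (SE 0.51) at 15 min and 2.01 at 30 min. The related factors dbf2 and DBP1a rose by 1.38 (SE 0.17) and 0.86 (SE 0.11) at 15 min. At 5 min expA3 fell by 1.69 (SE 0.18, 4 reoriented and 4 vertical arrays), mpao1 by 1.54 (SE 0.30), piip1 by 1.57 (SE 0.37) and aos1 by 1.08 (SE 0.18). These means join both sides, and expA3 and mpao1 fell mostly in the upper side. In seasons 1 and 2 expA3 had a log2 signal of 9.434 and 9.541 in the upper side, and 11.657 and 11.705 in the lower. For mpao1 these were 7.826 and 8.201, and 9.909 and 10.428. The upper values of season 1 come from the doubted array. Total RNA of that powder stood at 12.184 for expA3 and 10.202 for mpao1, and of the season 2 upper powder at 9.012 and 8.347. At 5 min gst31 rose by 1.60 (SE 0.30), gst2 by 1.36 (SE 0.34) and LOC606403 by 1.30 (SE 0.30). Here too the upper side stood higher for gst31 and gst2, with lower minus upper differences of -1.82 and -2.04. PPCK1 fell by 1.01 (SE 0.16), mpao1 by 1.37 and rs2 by 0.96 at 15 min. OEE3 fell by 1.04 (SE 0.21), psan1, of photosystem I, by 0.90 (SE 0.25) and LOC541946 by 0.77 (SE 0.22) at 30 min. At 60 min aos1 rose by 0.98 (SE 0.18), opr7 by 0.55 (SE 0.13) and glu1 by 1.19 (SE 0.31). At 60 min expA3 fell by 0.78, lkrsdh1 by 0.80 and prpo2 by 0.71. The inositol kinase gene lpa3 rose by 0.57 (SE 0.14) at 30 min.

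The polysomal counts were 6 at 2 min (1 after quantile normalization), 287 at 5 min (128 higher, 159 lower), 865 at 15 min (556 and 309), 620 at 30 min (422 and 198) and 551 at 60 min (316 and 235). With the plant pool as a random block they were 0, 58, 399, 258 and 154, where limma's unadjusted p under 0.05 was met by 767 probe sets at 2 min, and without the replicate block 2, 27, 315, 136 and 55. Without the doubted array 0 (1340 at an unadjusted p under 0.05 with it), 92, 1047, 801 and 701 passed, and dbf1 at 2 min missed with an adjusted p of 0.0590. The calls of gst2, LOC606403 and piip1 at 5 min were lost without it as well, with adjusted p of 0.129, 0.111 and 0.0762, and dbf1 at 5 min with 0.0772. With the pool block, calls were lost for dbf1 at 2 min (adjusted p = 0.134) and for dbf1, piip1, gst31, LOC606403 and gst2 at 5 min (0.0652, 0.0690, 0.0743, 0.125 and 0.196). Lost as well were rs2 at 15 min (0.0988) and tip2, psan1, lpa3 and LOC541946 at 30 min (0.0651, 0.0842, 0.0947 and 0.113). At 60 min lkrsdh1, glu1, opr7, expA3, gst30 and prpo2 were lost (0.0600, 0.0870, 0.0916, 0.102, 0.112 and 0.213). The other calls of the preceding paragraph held with it, but mpao1 and aos1 at 5 min missed with the doubted array left out as well (adjusted p = 0.101 and 0.0789). The count at 2 min was 84 without the left vertical array of season 1. At 5 min it was 690 and 53 without the upper and lower arrays of season 2, at 15 min 459 without the upper array of season 2, and at 30 and 60 min 222 and 159 without the lower array of season 1. Changes shrank for gst2 at 5 min (0.84 without the doubted array) and LOC541946 at 30 min (-0.49 without the upper array of season 1). At 60 min glu1 was 0.79 without the left vertical array of season 2.

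**Figure D3:**
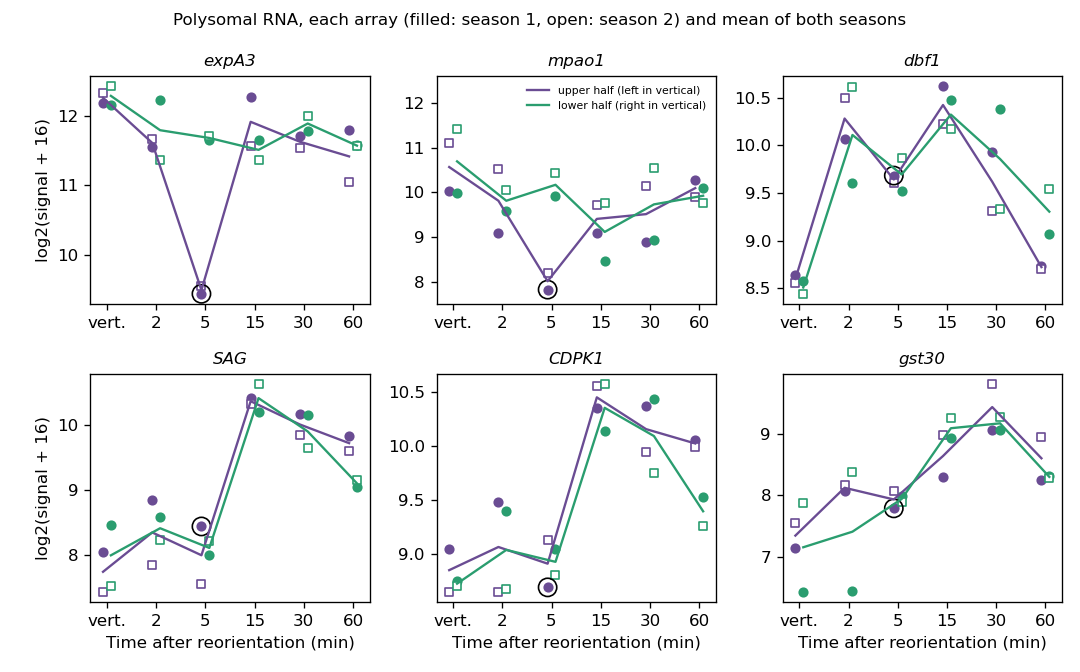
Log2 of polysomal signal plus 16 of 6 genes in vertical plants (vert.) and at each time after reorientation in min, with filled circles for season 1, open squares for season 2 and lines for the mean of both seasons per side. The ringed point is the doubted array; expA3 dips in the upper side at 5 min, and SAG and CDPK1 rise at 15 min.

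The gene lists moved by small amounts in the same comparison. In total RNA averaged over times 0 of 18 lists passed camera (lowest adjusted p = 0.269). In polysomal RNA averaged over times, 1 of the 5 early stress transcription factor probe sets rose (3 adjusted over the list alone), led by DBP1a (0.40) and dbf2 (0.48, adjusted p = 0.0510). The list was higher by camera (adjusted p = 0.0108, 0.372 as adjusted p with an estimated correlation). Of 31 aquaporin and ion transport probe sets 24 lay lower, 2 rose and none fell over all probe sets tested (2 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0095, adjusted p = 0.507 with an estimated correlation). At 15 min 5 of them fell, among them pip2c (-0.72), pip2b (-0.68) and PIP1-3 (-0.74), and 1 rose (2 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.00146, adjusted p = 0.508 with an estimated correlation). With the plant pool as a random block 0 early stress and 1 aquaporin and ion transport probe sets rose for the mean. At 15 min 3 of the latter then fell and 1 rose. Auxin response (0 of 6, 2 lower adjusted over the list alone), sucrose and starch metabolism (0 of 14, 0 over the list alone), cytoskeleton (0 of 30, 0 over the list alone) and green tissue markers (0 of 23, 0 over the list alone) were lower, with camera adjusted p of 0.0095, 0.0295, 0.0101 and 0.0095, and adjusted p = 0.496, 0.470, 0.496 and 0.507 with an estimated correlation. The leading members of the auxin list were abp1 (-0.50), ABP3 (-0.18) and abp4 (-0.17). ABP3 is an actin-depolymerizing factor. Without it 3 genes were left, too few for a test, so the call is not one of auxin genes alone. Without members of another function sucrose and starch metabolism missed (adjusted p = 0.0551).

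At single times the jasmonate, ethylene and wound list rose at 60 min. In total RNA 2 of its 15 probe sets rose (7 adjusted over the list alone), aos1 and opr7, and aoc1 at 0.50 missed with an adjusted p of 0.0523, and in polysomal RNA 3 (4 adjusted over the list alone). Camera gave adjusted p of 0.0172 and 0.0137, and adjusted p = 0.683 and 0.424 with an estimated correlation. With the plant pool as a random block 1 of these 15 probe sets rose in each RNA. The dehydrin gene dhn2 in polysomal RNA rose by 1.21 (SE 0.29) at 30 min and 1.12 at 60 min, and 3 of 5 abscisic acid and drought probe sets rose at both times (3 adjusted over the list alone, camera adjusted p = 0.0460 and 0.0477, adjusted p = 0.406 and 0.426 with an estimated correlation, 0.0581 and 0.0748 without the doubted array). These 5 probe sets cover 3 genes, and with the plant pool as a random block 2 rose at 30 min and 0 at 60 min. On means of plant pools camera missed at both times (adjusted p = 0.0606 and 0.0780). At 2 min that list was already higher, by 1.06 on average (0 of 5 called, 4 higher adjusted over the list alone, camera adjusted p = 0.000947, adjusted p = 0.277 with an estimated correlation). At 5 min it was lower, by 0.64 on average (0 of 5 called, 3 lower adjusted over the list alone, camera adjusted p = 0.0447, adjusted p = 0.767 with an estimated correlation, 0.0602 on means of plant pools). Green tissue markers were lower at 30 min in polysomal RNA, where 3 of 23 fell and 1 rose, led by OEE3, lhcb5 (-0.48) and psan1 (10 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00579, adjusted p = 0.406 with an estimated correlation). With the plant pool as a random block 1 green tissue probe set fell and 1 rose at 30 min. Calcium signalling (1 of 17 rose, 6 adjusted over the list alone, CDPK1) and inositol and phospholipid signalling (1 of 6, 2 over the list alone, lpa3) were higher at 30 min, each with camera adjusted p = 0.0460, adjusted p = 0.406 with an estimated correlation and 0.0506 without the doubted array. With the pool block 1 and 0 of their probe sets rose. On means of plant pools both lists missed by camera (adjusted p = 0.0525). Ribosomal proteins were higher at 60 min in polysomal RNA, where RPL19 (0.35) was the 1 of 19 that rose (1 over the list alone, 0 with the pool block, camera adjusted p = 0.00925, adjusted p = 0.424 with an estimated correlation). Cytoskeleton probe sets, 30 from 22 genes, were lower at 2 min, 27 of 30 in polysomal RNA (0 called, 4 lower adjusted over the list alone, camera adjusted p = 1.77e-07, adjusted p = 0.117 with an estimated correlation). In total RNA 28 of 30 were lower (0 called, 3 lower adjusted over the list alone, camera adjusted p = 0.000261, adjusted p = 0.348 with an estimated correlation). Cell wall remodelling probe sets were lower at 5 min in polysomal RNA, where 3 of 35 fell (2 with the pool block, 3 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.000560, adjusted p = 0.134 with an estimated correlation). So were sucrose and starch probe sets (0 of 14 called, 0 over the list alone, camera adjusted p = 0.00558, adjusted p = 0.134 with an estimated correlation). Cell cycle and histone, lignified tissue and epidermis lists had camera adjusted p of at least 0.303, 0.103 and 0.112 in every contrast of total and polysomal RNA.

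In the fit with season alone, the lower and upper sides differed past the threshold at 1 time, in polysomal RNA at 5 min. With the plant pool as a random block, total RNA also gave 4 probe sets at 15 min and 28 at 60 min, and 2 between vertical sides. Polysomal RNA then also gave 1 at 60 min. Polysomal RNA at 5 min passed in both fits. There the lower side had more of the expansin transcripts expA3 (2.19 log2 units, SE 0.25, 2 lower against 2 upper arrays, 2.22 and 2.17 in the 2 seasons, adjusted p = 0.00104), expB4 (2.33, SE 0.52), expB5 (2.07, SE 0.46) and expB8 (1.04, SE 0.20), and more LOC732784 (2.49, SE 0.55). The upper side had more of gst2 and gst31 (-2.04, SE 0.48, and -1.82, SE 0.43), of krp6, a kinesin gene (-1.50, SE 0.29), and of rbohB, for an NADPH oxidase (-1.08, SE 0.19). The season 1 value of 2.22 rests on the doubted array. In total RNA of the same powders expA3 differed by 1.32 (SE 0.60), which did not pass, with -0.31 in season 1 and 2.95 in season 2. Right and left sides of vertical plants differed by 0.03 (SE 0.25) for polysomal expA3.

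At 5 min 298 polysomal probe sets passed (218 higher, 80 lower in the lower side), 1261 with the plant pool as a random block and 5 without the replicate block. Without the doubted upper array of season 1, 6 passed, of which expA3 was the named one (2.05, adjusted p = 0.0394), and 158 with the pool block as well. Without it and without the pool block, the call of every other gene named here was lost, with adjusted p from 0.268 to 0.525. With the pool block as well expB4, expB5, expB8 and rbohB passed (adjusted p = 0.0264, 0.0368, 0.00880 and 0.0127), against 1 upper array. In that fit krp6, LOC732784, gst2 and gst31 missed (adjusted p = 0.0703, 0.0944, 0.157 and 0.173). Without that array LOC732784 differed by 1.51, expB4 by 1.10, gst2 by -0.998 and gst31 by -0.94. The count was 19 without the lower array of season 1, and 1508 and 116 without the upper and lower arrays of season 2, while expA3 passed in each of the 4 fits.

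Cell wall remodelling probe sets were higher in the lower side at 5 min in polysomal RNA, where 7 of 35 rose and none fell (12 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0286). That call held without the doubted array (adjusted p = 0.000854), where 1 of 35 passed the gene test. It did not hold without the replicate block (adjusted p = 0.0673) or with an estimated correlation (adjusted p = 0.452). In total RNA at 5 min the same list was higher by camera (adjusted p = 0.0166, adjusted p = 0.167 with an estimated correlation) with 0 of 35 probe sets past limma's test or adjusted over the list alone. Its mean change was 0.19 and its median 0.04, and without members of another function its adjusted p was 0.136. Its leading members were prp2 (1.00), a pathogenesis-related gene, expB4 (0.76) and expB5 (0.82). Redox (0 higher and 3 lower of 29, 8 lower adjusted over the list alone), cytoskeleton (1 lower of 30, 4 over the list alone) and heat shock lists (0 of 8, 0 over the list alone) were lower at 5 min, with camera adjusted p of 8.18e-05, 0.00761 and 0.0372 and adjusted p = 0.452, 0.452 and 0.518 with an estimated correlation. Without the doubted array these were 0.158, 0.0648 and 0.903, and heat shock missed after quantile normalization (adjusted p = 0.0817).

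For the mean over times, limma found 0 probe sets that differed between the sides in either RNA, where 146 in total and 475 in polysomal RNA had an unadjusted p under 0.05. The smallest p values of named genes belonged in total RNA to MPK4 (-0.30, SE 0.08), LOC542037 (0.29), fad7 (-0.29), gst13 (0.35), gst17 (0.15) and MMT1 (-0.16). In polysomal RNA they belonged to expA3 (0.48, SE 0.11), LOC606477 (0.48), LOC100037796 (0.25), mez2 (0.25), zmCL2-2 (0.24) and PPCK1 (0.29), none past the threshold. At 2, 5, 15, 30 and 60 min limma also gave 0 in total RNA (104, 146, 151, 79 and 261 unadjusted) and, but for 5 min, 0 in polysomal RNA (53, 92, 62 and 181 unadjusted). The right and left sides of vertical plants gave 0 as well (131 in total and 133 in polysomal RNA unadjusted). With the plant pool as a random block total RNA gave 4 probe sets at 15 min (1.70, -0.64, 1.25 and 0.85), 28 at 60 min and 2 between the vertical sides (0.89 and 1.25). With it polysomal RNA gave 1 at 60 min (2.07). The 4, 2 and 1 have no listed gene and were chosen after their values were seen. Lower minus upper changes of the 2 seasons correlated across probe sets at r = 0.321 and 0.322 at 60 min in total and polysomal RNA. For right minus left these were 0.045 and 0.002. At 2, 5, 15 and 30 min they were 0.125, 0.064, 0.132 and -0.096 in total RNA. In polysomal RNA they were -0.015, 0.44 (with the doubted array), -0.241 and 0.036. Without the season 2 upper 5 min array 22 passed for the polysomal mean, and without the season 1 upper array 5 passed at 5 min in total RNA.

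By lists, cytoskeleton and translation factor probe sets were higher in the lower side for the total RNA mean, by mean changes of 0.04 and 0.03, with 0 of 30 and 0 of 22 past the gene test or adjusted over the list alone (camera adjusted p = 0.000492 and 0.0139, adjusted p = 0.248 and 0.248 with an estimated correlation). After quantile normalization both missed (adjusted p = 0.330 and 0.443). In polysomal RNA translation factors were higher in the lower side at 30 min and lower at 60 min (camera adjusted p = 0.00065 and 0.0381). The jasmonate, ethylene and wound list was lower at 60 min in total and polysomal RNA (camera adjusted p = 0.0486 and 0.0381). These had 0 members past the gene test and adjusted p of 0.493 to 0.647 with an estimated correlation. Not all single-time list calls between the sides are given. Redox genes were lower in the polysomal mean, by 0.14 on average, with 0 of 29 past the gene test (0 adjusted over the list alone, camera adjusted p = 0.000744, adjusted p = 0.608 with an estimated correlation), and with an adjusted p of 0.186 without the doubted array. Lists also passed camera between right and left sides of vertical plants in polysomal RNA, where cell wall, ribosomal protein, translation factor and aquaporin lists were lower on the right with 0 members past the gene test or adjusted over the list alone (camera adjusted p = 0.0177, 0.000596, 0.0177 and 0.0404, adjusted p = 0.538, 0.538, 0.538 and 0.915 with an estimated correlation). These 4 missed after quantile normalization, with adjusted p of at least 0.136.

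Polysomal and total RNA were compared within each powder, to ask how the share of a transcript on polysomes differs between genes. Each kind of RNA came from its own aliquot and preparation. A difference made by the preparation cannot be told apart from one of that share. Higher in polysomal RNA were the methyltransferase gene pOMT1 (1.14, SE 0.06, 24 powders), Snf-4 like (1.03, SE 0.07), lpa1 (LOC100125659, 0.90, SE 0.04), akin1 (0.87, SE 0.05), and the sucrose transporter gene sut1 (0.81, SE 0.05). So were CDC5 (0.76), the starch synthase gene ss1 (0.75), KIN9 (0.73), TOR (0.72) and pglcat8 (0.72). Lower were the ribosomal protein gene RPL19 (-1.12, SE 0.05), LOC541944 (-1.11, SE 0.11), the tubulin gene TUA1 (-1.08, SE 0.07), the proton pump gene mha1 (-1.07, SE 0.09), and the cyclin gene cycD2 (-0.93, SE 0.05). So were ubc7 (-0.88), mir3 (LOC100037824, -0.83), nfa104 (-0.82), the histone deacetylase gene hdt103 (-0.81) and LOC732737 (-0.77). Each of the 20 kept its sign in both seasons, as the naming rule requires. All 20 passed without any 1 array and with the plant pool as a random block, with adjusted p of at most 4.08e-06 among fits without 1 array. Arrays were scaled to 1 level, so each value is relative to the other transcripts of its array.

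In this comparison 7537 probe sets passed (4432 higher, 3105 lower), 7206 with the plant pool as a random block on the differences and 7766 without the doubted array, and the ratios of the 2 seasons correlated at r = 0.827 across probe sets. Of 19 ribosomal protein probe sets 12 were lower and 2 higher (12 and 2 adjusted over the list alone), led by RPL19, rps27 (-0.57) and rpl30 (-0.69). Camera gave an adjusted p = 0.00364 and adjusted p = 0.366 with an estimated correlation. All 6 inositol and phospholipid probe sets were higher (6 adjusted over the list alone), among them lpa1 (LOC100125659), a transporter gene, PLC (0.45, SE 0.04) and lpa2 (0.35, SE 0.04), with camera adjusted p = 0.0421 and adjusted p = 0.366 with an estimated correlation. Without members of another function 4 genes were left, too few for a test. Of the genes followed earlier in this organ, crt2, a calreticulin (0.37, SE 0.03), incw1, a cell wall invertase (0.31, SE 0.04), lpa3 (0.29, SE 0.05) and PLD1 (0.21, SE 0.04) were higher in polysomal RNA, while cal2 and ivr2 did not pass. For reoriented against vertical plants, averaged over times, none of these genes passed in total RNA: crt2 0.11, cal2 -0.002, ivr2 -0.32, incw1 0.21, PLD1 0.27, PLC -0.03 and lpa3 0.22. The ivr2 mean joins 1.27 in season 1 and -1.91 in season 2, and in polysomal RNA these were 1.18 and -2.07. That difference was not tested.

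**Figure D4:**
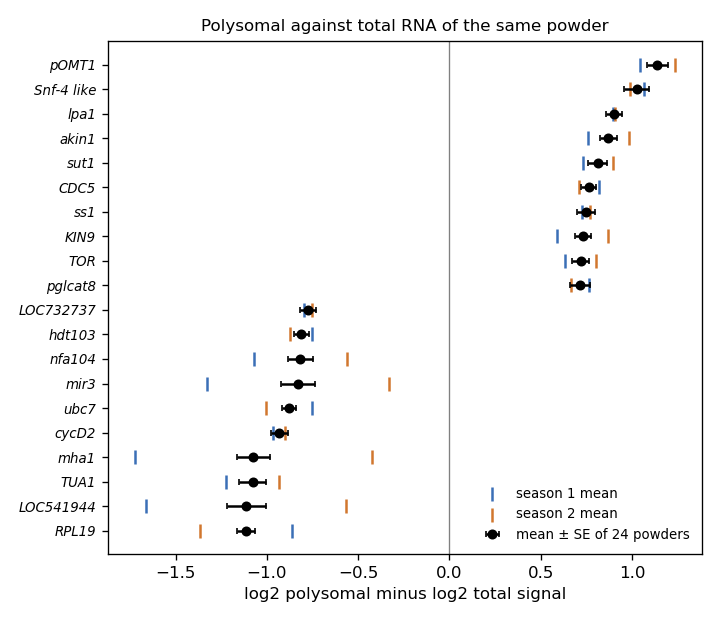
Log2 polysomal minus log2 total signal of the 20 genes named by the rule, as the mean of 24 powders with its SE (points) and as the mean of each season (ticks). The highest is pOMT1 (1.14) and the lowest RPL19 (-1.12).

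Changes of the polysomal share with reorientation were not detected for single probe sets at this number of arrays. Limma found 0 probe sets whose ratio changed for the mean of the 5 times (451 at an unadjusted p under 0.05) or at any time by the moderated F (927 unadjusted), and 0 whose ratio differed between lower and upper sides for the mean (357) or at any time (337). The 1 model of all 48 arrays gave 12 for any time against vertical plants. Without the season 2 upper 5 min array of either RNA these counts rose, except for the mean against vertical plants. The upper 5 min powder left then pairs the doubted polysomal array with total RNA that lies with season 1. Such counts therefore cannot be read as a change of the ratio. Some lists moved in the ratio with 0 members past the gene test, at single times as well as for the means. At 60 min ribosomal proteins were higher in reoriented plants (17 of 19, camera adjusted p = 0.000724) and lower in the lower side (camera adjusted p = 0.0108). With an estimated correlation the adjusted p values were 0.618 and 0.539. Not all single-time list calls are given. For the mean against vertical plants auxin response, cytoskeleton and sucrose and starch lists were lower, with 0 adjusted over the list alone. Camera gave adjusted p of 0.00303, 0.0275 and 0.0407, and adjusted p = 0.414, 0.436 and 0.414 with an estimated correlation. After quantile normalization all 3 missed (adjusted p = 0.125, 0.473 and 0.117). Without members of another function cytoskeleton and sucrose and starch missed (adjusted p = 0.148 and 0.1504), and the auxin list was too small for a test. Sucrose and starch also missed without the doubted array (adjusted p = 0.0769). In the lower against the upper side cytoskeleton, redox and heat shock lists were lower (0, 1 and 0 lower adjusted over the list alone). Camera gave adjusted p of 0.000128, 0.00209 and 0.00812, and adjusted p = 0.223, 0.492 and 0.492 with an estimated correlation. Without the doubted array these were 0.0184, 0.664 and 0.594, and cytoskeleton missed after quantile normalization (adjusted p = 0.0968). Log2 changes of total and polysomal RNA against vertical plants correlated at r = 0.859 across probe sets for the mean of times. In both RNAs 160 probe sets rose and 37 fell for that mean, against 7.68 and 1.51 expected from independent draws, and these RNAs come from the same powders. At 15 min 344 rose and 136 fell in both, against 28.5 and 12.2 expected.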

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

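Tests chosen only after the result was seen are the swap with an array of season 2, the pool correlation of the sides, the expA3 value without the doubted array, the fits without that array, a pool block on the powder differences, and list tests on named probe sets, on pool means and without members of another function.

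Changes from vertical plants differed between the 5 times in 1806 probe sets of total RNA and 1531 of polysomal RNA by limma's moderated F, and in 393 and 617 with the plant pool as a random block. The polysomal counts were 1342 and 460 without the doubted array. The cell wall invertase gene incw1 was higher in reoriented plants in season 1 and lower in season 2 in both RNAs. The changes of season 2 minus season 1 were -1.36 in total and -1.417 in polysomal RNA, and this difference was not tested. Every sample moved one way in season 1 and the other way in season 2 in 62 probe sets of total RNA, and one way in both in 80. In polysomal RNA these were 36 and 86.

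The polysomal array labelled upper side, 5 min, season 1 lay with the other season. On a scale of 0 for the season 1 mean and 1 for the season 2 mean it stood at 0.964, where the other 23 arrays of season 1 lay between -0.119 and 0.184 and the 24 of season 2 between 0.80 and 1.118. The tables argue against a swap with an array of season 2, since 0 of those lay nearer season 1, against scaling, since its median r with season 2 stayed 0.0501 above that with season 1 after quantile normalization, and against a mixture of both seasons, since 0.964 is close to 1. A mislabelled sample may be the cause and met its prediction at 0.964. For a response of the upper side, total RNA of that powder stood at 0.11, between the limits set beforehand, so that prediction was not decided. The value lies among the other season 1 arrays, so no shift of that powder was seen in total RNA. A response in polysomal RNA alone cannot be told apart from a mislabelled sample. The 5 min differences of redox, heat shock, expB4 (-2.46), LOC732784 (-2.26), gst2 (1.86), gst31 (1.64) and expB5 (-1.58, total RNA) transcripts fall in groups that differ between seasons, and if the array came from season 2, the season values of expA3 are not independent.

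More probe sets passed in reoriented against vertical plants than with the plant pool as a random block, 372 against 45 in total and 454 against 152 in polysomal RNA. The 2 fits differ only in this block, so the gap comes from counting the sides of a pool as separate plants. The lower correlation of the sides, in polysomal RNA, was 0.3805, and 0.504 without the doubted array. The value of 0.3805 met a prediction written after the result was seen. With another time placed as the control, counts reached 768 in total RNA (15 min) and 1061 in polysomal RNA (5 min), 2.337 times that with the vertical plants at most. Pools that differ for another reason than reorientation would do this, and so would a course over time, and both stay open.

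The higher expA3 in the lower side at 5 min in polysomal RNA was 2.05 log2 units without the doubted array, against 2.19 with it, but that value rests on 1 upper array. Total RNA of the same powders gave -0.31 in season 1 and 2.95 in season 2. The doubted array as the cause cannot be told apart from a difference between the sides.

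For reoriented against vertical plants averaged over times, the regroupings cannot exclude chance and cannot measure it either. They exchange time labels among pools that themselves differ between times, so they are not draws without any effect. In total RNA 13 of 100 regroupings of the plant pools, the real one among them, gave as many probe sets as the real 372, with up to 1024 in another, and in polysomal RNA 5 did, with 454 real and up to 719. Such counts point to a structure among the pools, such as time. Where the real count is 0, every regrouping reaches it, so these shares say nothing about chance. That was 100 of 100 for the lower against the upper side in each RNA (146 and 475 by limma at an unadjusted p under 0.05), with up to 0 and 1 in others. For the polysomal over total ratio it was 100 of 100 for the lower against the upper side (357 unadjusted, up to 0) and for reoriented against vertical plants (451 unadjusted, up to 94). For polysomal against total RNA 1 of 100, the real one, gave 7537, and others gave 0. That argues against chance labels only. A steady difference between the kinds of RNA would give such counts whatever its cause, the preparation of the RNA included.

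At single times the 2 splits of the pools are too few for a share under 0.05. The real and the other count in total RNA were 7 and 11 at 2 min, 6 and 24 at 5 min, 953 and 5 at 15 min, 539 and 0 at 30 min, and 419 and 3 at 60 min. In polysomal RNA they were 6 and 2, 287 and 0, 865 and 0, 620 and 5, and 551 and 2.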

How the results depend on the processing

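Fits without the doubted array, alone or with a pool block, and the pool block on powder differences were chosen after seeing the data. Counts moved with how sides and seasons were modelled and with single arrays, 1 called list turned direction, and the cause of each change was not tested except where stated. Arrays have no read depth; 15.0% to 22.4% of probe sets per array had a signal under 16, where small changes are not resolved.

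Values are probe sets past the threshold, for reoriented against vertical plants unless stated. With a pseudocount of 64, 13 passed at 2 min in total and 2 in polysomal RNA. Without a filter 10 passed at 5 min in total and 2 at 2 min in polysomal RNA. With the filter at the 60th percentile, which tests fewer probe sets, total RNA gave 183 for the mean, 12 at 2 min, 595 at 15 min and 348 at 30 min, and polysomal RNA 281 for the mean, 567 at 15 min and 378 at 30 min. After quantile normalization total RNA gave 60 at 2 min (58.3% higher, 85.7% as deposited) and 23 at 5 min (65.2% higher, 100% as deposited), and polysomal RNA 1 at 2 min. eBayes without a trend gave 14 at 2 min in total RNA.

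Without the replicate block total RNA gave 52 for the mean and 1, 3, 266, 87 and 28 at 2, 5, 15, 30 and 60 min, and polysomal RNA 116 and 2, 27, 315, 136 and 55, with 5 for lower against upper at 5 min. With the plant pool as a random block total RNA gave 45 for the mean and 1, 2, 293, 113 and 34, and polysomal RNA 152 and 0, 58, 399, 258 and 154. Lower against upper then gave 4 at 15 min and 28 at 60 min in total RNA, and 1261 at 5 min and 1 at 60 min in polysomal RNA, and right against left 2 in total RNA. The model of 48 arrays gave 12 for the ratio at any time.

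Without the doubted array polysomal RNA gave 0 at 2 min, 92 at 5 min and 6 for lower against upper at 5 min. With the pool block as well it gave 149 for the mean and 0, 6, 390, 247 and 141, and for lower against upper 158 at 5 min and 14 at 60 min. Season 1 alone gave 39 for the mean in total and 0 in polysomal RNA, and season 2 alone 153 and 193, with fewer arrays. The upper against the left side gave 69 and 87, the lower against the right side 13 and 45.

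Leaving out 1 array, where a lone array is assumed to vary like the other groups, gave ranges in total RNA of 79 to 427 for the mean and 1 to 144, 0 to 63, 545 to 1011, 151 to 613 and 127 to 374 at the 5 times, 0 to 5 for lower against upper at 5 min and 0 to 1 for right against left. In polysomal RNA it gave 117 to 586, then 0 to 84, 53 to 690, 459 to 672, 222 to 747 and 159 to 365. Lower against upper gave 0 to 22 for the mean, 6 to 1508 at 5 min and 0 to 2 at 60 min, and right against left 0 to 1. Polysomal against total RNA gave 7294 to 7766. The ratio gave 0 to 664 for any time against vertical plants, 0 to 235 for the mean of lower against upper and 0 to 592 for any time of it.

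Of 111 calls of named genes 108 held with a pseudocount of 1, 108 with 64, 94 without a filter, 104 after quantile normalization, 48 without the replicate block and 105 without a trend. With the pool block 35 of 86 held, at the 60th percentile 73 of 79, without the doubted array 66 of 75, with both changes 17 of 50, and in fits without 1 array 2012 of 2392. In season 1 alone 0 of 33 held, in season 2 alone 11, for the upper against the left side 6 and for the lower against the right side 3. Of 67 list calls, those between seasons left aside, 0 held with an estimated correlation, 42 after quantile normalization, 59 without the replicate block and 58 against named probe sets alone. Without members of another function 49 of 56 held, on pool means 31 of 36 and without the doubted array 40 of 52. Apart from these, the heat shock list turned direction at 5 min in the ratio of lower against upper. It was lower (adjusted p = 0.00278, adjusted p = 0.740 with an estimated correlation) and, without the doubted array, higher (adjusted p = 0.633).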

Other observations

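Many probe sets differed between the growing seasons, compared with 12 arrays from 6 plant pools per season in each RNA. In total RNA 5969 of 10527 probe sets differed between seasons (2457 higher and 3512 lower in season 2, limma adjusted p), and in polysomal RNA 5850 (2667 and 3183). With the plant pool as a random block these were 4559 (1877 and 2682) and 4909 (2262 and 2647). Polysomal RNA without the doubted array, whose season is in question, gave 6121 (2725 and 3396), and 5091 with the pool block as well. The small heat shock protein genes hsp18f and hsp22 were higher in season 2 by 3.06 (SE 0.20, 0.21 with the pool block) and 2.77 (SE 0.35) log2 units in total RNA, hsp18c by 2.49, the chaperone gene hsp101 by 2.03, gst19 by 2.71 and the aquaporin gene pip2d by 2.36. Lower in season 2 were nar (-3.06, SE 0.26), NIR, for nitrite reductase (-1.60, SE 0.15), the expansin genes expB4 (-2.73, SE 0.12) and expB5 (-1.58, SE 0.14), LOC732784 (-2.28), TPS9 (-2.18) and pdc1, for pyruvate decarboxylase (-1.87).

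Of 8 heat shock and chaperone probe sets 6 were higher in season 2 in total RNA (camera adjusted p = 0.00253, adjusted p = 0.559 with an estimated correlation). Of 29 redox probe sets 20 were higher and 3 lower (adjusted p = 1.68e-05, adjusted p = 0.0203 with an estimated correlation and 0.161 with it on means of plant pools). In polysomal RNA 20 were higher and 4 lower (adjusted p = 2.49e-05, adjusted p = 0.731 with an estimated correlation), and without the doubted array 21 and 4 (adjusted p = 4.45e-06, adjusted p = 0.700 with an estimated correlation). Of 23 green tissue probe sets 14 were higher and 2 lower in total RNA (camera adjusted p = 0.0180, adjusted p = 0.878 with an estimated correlation). In polysomal RNA 13 were higher and 2 lower (camera adjusted p = 0.00967, adjusted p = 0.731 with an estimated correlation). Season stands for all that differed between the repetitions, including growth and array handling, and these were not separated here.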
